A study of Homo sapiens with 2 samples.

How the data were processed

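Total RNA of MRC-5 cells, 1 dish without and 1 dish with 50 ng/mL of IL-13 for 24 h, was labelled with Cy3 and hybridised to 1 one-colour Agilent array each, per the labels' protocols. Images were quantified with Agilent Feature Extraction 11.5.1.1, per the submitters' processing notes. The values used here are the processed signal of each spot, a linear intensity that had been background-subtracted and spatially detrended within each array before it was deposited, per the file headers. They were not normalized between arrays. A further deposited table held the authors' own values, also a linear intensity. Set against the scanner values spot by spot, these equalled the processed signal times 1 constant per array, 2.8436 for the unstimulated and 3.104 for the IL-13 array, with a relative range of 9.9e-10 within each array. Their medians were 105.4 and 92.8. They are on a linear scale and not centred, and how the constants were chosen remains unknown. Array annotation refers to genome build hg19, per the file headers. Both arrays came from 1 slide and were scanned on the same day, so slide and day do not separate the groups.

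The processed signal was taken to log2 and each array's 75th percentile over non-control spots was subtracted. Of 62976 spots, 58717 were not controls. Spots marked as non-uniformity or population outliers, 307 on the unstimulated and 251 on the IL-13 array, were left out, saturated spots would have been kept but there were 0, and spots of one probe were averaged, which gave 50590 probes. A total of 902 probes were printed 10 times and the rest once. The negative controls had an SD of 2.4 and 2.04 intensity units, the spike-in dose fit an R squared of 0.991 and 0.992, and replicate spots a median coefficient of variation of 4.21% and 4.04%, in the same order of arrays. The 100 brightest spots held 14.5% and 14.7% of the signal. The spread between replicate spots covers spotting and scanning within an array only and leaves out culture, labelling and hybridisation.

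The scanner files give an accession for each probe and no gene symbol. Accessions were matched without their versions to a RefSeq gene table of assembly GRCh38.p14, which gave a symbol to 29998 probes and none to 20592. Since the array annotation and this table refer to different builds, the table was used for names only and no positions are given. IFI27, ALDOA, MUC5AC, LYZ and AIF1 had no matching accession and were not analysed here. For each of the 21609 genes the probe with the highest mean signal stood for the gene. A gene counted as measured when that probe was well above background on both arrays by the scanner software's call (15080 genes), and 5530 genes were not well above background at any probe on either array. Of 3965 genes with at least 2 measured probes, 67 had probes of opposite sign more than 1 log2 unit apart. Of 38 such genes beyond 2-fold, 32 had all probes in the same direction. For genes with all probes below background on 1 array, a lower bound of the fold was computed from the bright array's value against the higher of the dim probe's own value and the lowest signal among probes well above background on the dim array.

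Differences are IL-13 minus unstimulated on the log2 scale, and 2-fold was the threshold for counts. With 1 array per group no test was possible, and no p-value or standard error is given. The 25 gene lists, the threshold, the alternatives and the rule for named genes were set before the data were examined. The rule names the 10 genes with the largest positive and the 10 with the largest negative difference among genes measured on both arrays and not saturated on both, passing over names that are only an accession, a clone or a locus number. It further names the 5 genes with the largest bound in each direction, 8 genes in any case (SOX11, STAT6, IL13RA1, IL13RA2, IL4R, POSTN, CCL11 and CCL26), and from each list up to 4 measured members with the largest absolute difference. Some genes that the rule selects are not reported here. Each list's median was placed among the medians of 10000 random gene lists of the same size, matched on mean signal in 20 bins. Such a percentile describes these 2 arrays and is not a p-value. The lists cover the type 2 cytokine response, the receptor and JAK-STAT chain, SOX factors, matrix, contractile genes, TGF-beta response, metalloproteinases, CC and CXC chemokines, NF-kappaB, interferon, cell cycle, p53, immediate early, hypoxia, unfolded protein and amino acid stress, cholesterol, WNT and BMP, growth factors, complement, housekeeping and 4 sets of cell type markers. Some genes stand in more than 1 list.

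Processing alternatives were scaling to the median, to the 75th percentile of probes well above background, quantile normalization, cyclic loess, a normexp background with an offset of 50, the authors' values, other filters on dim, saturated and outlier spots, the median of a gene's probes, thresholds of 1.5-fold and 3-fold, unmatched random lists and list means. The scanner files used here hold the median and not the mean spot signal, so normexp was run on the median signal. The offset of 50 is added to every spot. It is above the median processed signal of both arrays (37.1 without and 29.9 with IL-13). It shrinks differences between dim spots by construction, so a smaller normexp difference at a dim gene does not by itself speak against that gene. Scaling to the E1A spike-in probes, whose 8 probes well above background were 0.13 ± 0.07 (SD over probes) higher on the IL-13 array, and a threshold of 3 SD between replicate spots were added after the values were seen.

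The counting steps were tested on simulated data in which 200 of 15070 genes of the IL-13 comparison were given known folds on top of replicate-spot noise. Of 50 genes set to 1.5-fold, 1 was counted as 2-fold, and of 50 each set to 2.5-fold, 4-fold and 8-fold, 48, 50 and 49 were counted, with median recovered folds of 2.48, 4.00 and 8.05. Calculations used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, R 4.3.3 with limma 3.58.1 for quantile, loess and normexp, and matplotlib 3.10.9 for the plots.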

Results

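RNA abundance was measured in MRC-5 cells, an established diploid fibroblast line from human lung, after 24 h in serum-containing medium. One dish received no cytokine and the other received 50 ng/mL of interleukin-13 (IL-13), a type 2 cytokine that acts on fibroblasts through the IL-4 receptor alpha chain, IL13RA1 and the transcription factor STAT6. Each condition was represented by 1 one-colour Agilent array of 62976 spots. On the unstimulated array 28588 of 50590 probes (56.5%) were well above background, and on the IL-13 array 27996 (55.3%). The 75th percentile of the processed signal was 488.6 without and 435.6 with IL-13, and no spot was saturated. The comparison addressed which transcripts differed in these fibroblasts after IL-13, with STAT6 and SOX11 as the regulators named in the study's title. With 1 array per group there was no replicate check, so sizes are given without tests, and the number of arrays limits the precision of every value.

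With IL-13, the transcript with the largest difference was CCL26 (eotaxin-3, a chemokine for eosinophils), which was 36.7-fold higher (log2 difference 5.20, or 4.58 with a normexp background correction). The heparan sulfate sulfotransferase HS3ST1 was 11.4-fold higher, averaged over 10 spots, and the ganglioside synthase ST8SIA1 11.1-fold higher (log2 difference 3.47, or 2.32 with normexp and 2.19 with the median of its probes). IL6, a proinflammatory cytokine, was 10.4-fold higher. CISH and SOCS1, feedback inhibitors of JAK-STAT signalling, were 9.22-fold and 6.50-fold higher. POSTN, encoding the matricellular protein periostin, was 5.26-fold higher (log2 difference 2.40), and the transcription factor SOX11 was 5.16-fold higher (2.37), while STAT6 itself differed by -0.08 on the log2 scale.

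**Figure D1:**
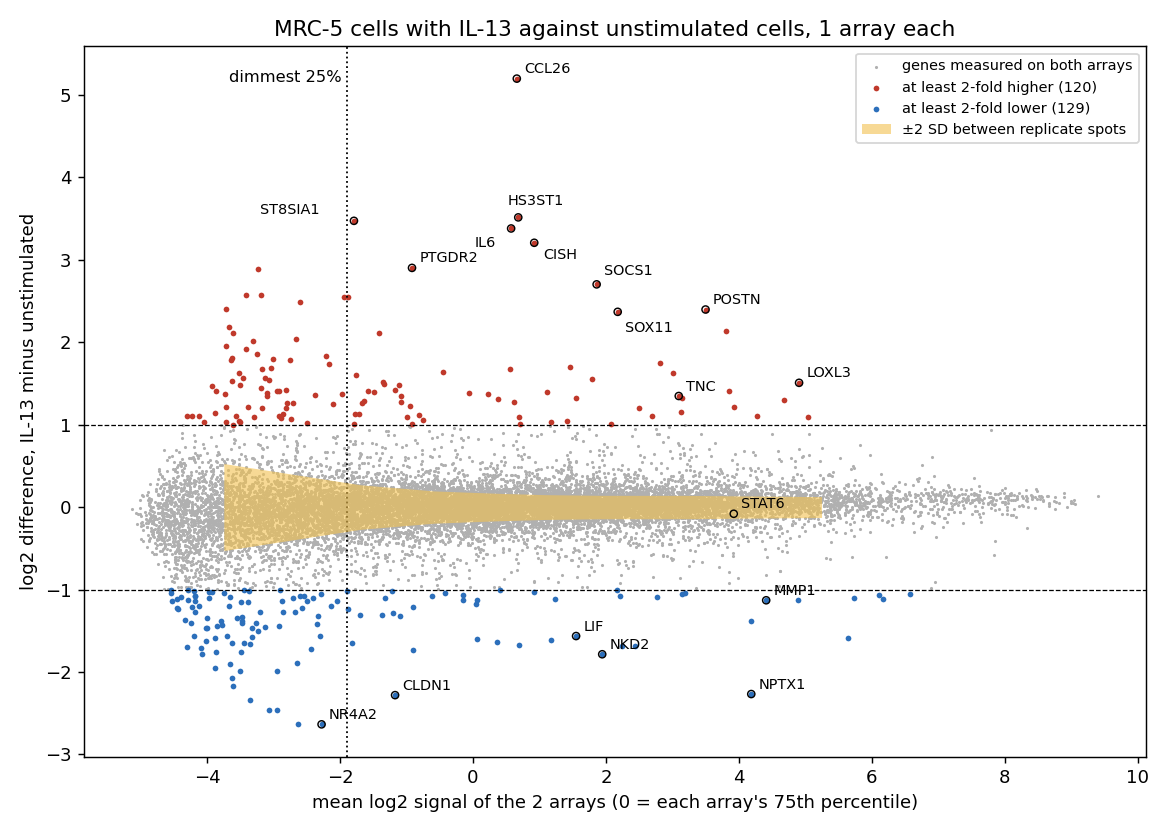
Log2 difference between the IL-13 and the unstimulated array (vertical axis) against the mean log2 signal of both arrays (horizontal axis, 0 at each array's 75th percentile) for each of the 15080 genes measured on both arrays; red and blue points are the 120 genes at least 2-fold higher and the 129 at least 2-fold lower, and the band spans 2 SD of the difference between replicate spots to each side of 0. CCL26 lies at 5.20, and most of the other genes beyond 2-fold lie left of the dotted line that bounds the dimmest 25% of genes.

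The rest of the 10 genes with the largest positive differences were PTGDR2 (a prostaglandin D2 receptor, 7.47-fold), the long noncoding RNA LINC00971 (7.42-fold), the axon guidance ligand SLIT2 (5.96-fold) and the synaptotagmin SYT8 (5.95-fold). Among the 10 genes with the largest negative differences, NPTX1 (neuronal pentraxin 1) was the brightest and was 4.82-fold lower with IL-13. The tight junction gene CLDN1 was 4.86-fold lower. The other 8 were the nuclear receptor NR4A2 (6.21-fold lower), the urea transporter SLC14A1 (6.20-fold), the potassium channel genes KCNK3 (5.52-fold) and KCNAB3 (3.98-fold), the ephrin receptor EPHA10 (5.50-fold), the angiotensin receptor AGTR1 (5.04-fold), AADACL3 (4.50-fold) and the atypical chemokine receptor ACKR4 (4.20-fold). These 8, with LINC00971, SLIT2 and SYT8, lay in the dimmest 25% of measured genes, where replicate spots also differed most. With normexp in place of the processed signal the log2 difference of PTGDR2 was 2.22 and that of CLDN1 -1.64. SYT8 (0.99), KCNK3 (-0.97), AGTR1 (-0.84), AADACL3 (-0.90), ACKR4 (-0.70) and KCNAB3 (-0.91) were then within 2-fold. SLIT2 (1.19), LINC00971 (1.03), EPHA10 (-1.002), SLC14A1 (-1.18) and NR4A2 (-1.44) remained beyond 2-fold. The offset of normexp shrinks dim differences by construction. A second probe of NR4A2 differed by -2.03 and a second probe of ST8SIA1 by 0.92. The values of CCL26, IL6, CISH, SOCS1, PTGDR2, LINC00971, SLIT2, SYT8, POSTN and SOX11 each came from a single spot. So did those of NPTX1, CLDN1, SLC14A1, KCNK3, KCNAB3, EPHA10, AGTR1, AADACL3 and ACKR4. SLC14A1 and AADACL3 had 2 and 1 other probes that were well above background on 1 array only. EPHA10 had 3 probes in all and LINC00971 had 2, and their other probes were not well above background on either array.

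Of 15080 genes measured on both arrays, 120 were at least 2-fold higher and 129 at least 2-fold lower with IL-13, together 249 or 1.65%. The higher group held 48.2% of these genes, and this split depended on the scaling and the background correction. Scaling to the median gave 179 higher and 80 lower genes (69.1% higher), scaling to the E1A spike-in probes gave 92 and 213 (30.2%), and a normexp background gave 50 and 33 (60.2%). The median log2 difference of all genes was 0.01 in the values reported here, 0.16 with median scaling and -0.12 with spike-in scaling, so the medians of gene groups that stood apart are also given relative to all genes, which such a shift leaves as they are. Taken without this, several medians turn sign, among them those of the NF-kappaB and the WNT and BMP lists with median scaling and those of the SOX, contractile and housekeeping lists with spike-in scaling. The SD of the log2 difference between replicate spots was 0.0867 at the median probe and ranged from 0.264 for the dimmest to 0.0632 for the brightest eighth of replicated probes.

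Genes described as induced by IL-4 or IL-13 stood highest of the 25 gene lists. Of 32 genes in the type 2 cytokine response list, 19 were measured on both arrays, 6 of them at least 2-fold higher and none 2-fold lower. With spike-in scaling, and with the authors' values, 1 was 2-fold lower. Of the 19, 14 lay above 0 and 5 below, the lowest being SERPINB2 (-0.98, named after its value was seen). The 6 higher genes were CCL26, CISH, SOCS1, POSTN, the matrix glycoprotein TNC (2.54-fold) and the adhesion molecule VCAM1 (2.35-fold, and log2 0.90 with normexp). The list's median of 0.51 lay 0.50 above all genes and above all 10000 random lists matched on signal, and 0.17 above all genes without a filter on dim probes. IL13RA2, the decoy receptor, was 1.47-fold higher, and CCL11 (eotaxin-1) was not well above background on either array.

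Of 30 measured genes of the IL-4 and IL-13 receptor and JAK-STAT list, CISH and SOCS1 were at least 2-fold higher and the other 28 were within 2-fold, with a median of 0.03 (percentile 71.4). IL13RA1 differed by 0.11 and IL4R by -0.04; the signs of IL4R and STAT6 turned with median scaling and that of IL13RA1 with spike-in scaling. The kinase JAK3 was 1.69-fold higher (log2 difference 0.76, or 0.47 with the median of its probes) and the adaptor IRS2 1.60-fold lower (log2 difference -0.68). The mean of the list, 0.22, which gives CISH and SOCS1 more weight, lay at percentile 99.9 of random means.

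Among SOX transcription factors, SOX11 was the single one of 10 members measured on both arrays beyond 2-fold. SOX15, named after its value was seen, was detected only without IL-13, at a bound of -1.80 on the log2 scale. SOX12, which forms the SoxC group with SOX4 (0.05) and SOX11, differed by 0.53 and SOX6 by 0.43, while SOX9, a regulator of cartilage genes, differed by -0.60. SOX12 and SOX9 were among the dimmest 25%, and with normexp they differed by 0.18 and -0.29. The list's median was 0.10 (percentile 96.0, or 99.2 with quantile normalization). Without a filter on dim probes the median of the SOX list relative to all genes was -0.07.

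The extracellular matrix list had a higher median with IL-13, with 26 of 46 measured members above 0 and 20 below. Of these 46, 4 were at least 2-fold higher, namely POSTN, TNC, the lysyl oxidase family member LOXL3 (2.84-fold) and the fibril-associated collagen COL14A1 (2.83-fold). The basement membrane collagen COL15A1, which falls outside the naming rule and was chosen after its value was seen, was the 1 member at least 2-fold lower (-1.14, or -0.99 with median scaling and -0.73 with normexp). With median scaling 7 members were at least 2-fold higher and 0 lower. COL1A1 (-0.06), COL1A2 (-0.01) and FN1 (-0.45), also named after their values were seen, lay below 0. The median of 0.15, which is 0.13 above all genes, exceeded all 10000 matched random lists. Both LOXL3 probes lay between 1.51 and 1.67, and the second COL14A1 probe differed by 0.69.

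No contractile or myofibroblast gene of 19 measured differed 2-fold. The largest differences were in the cadherin CDH11 (0.84) and the actin-filament proteins LMOD1 (0.51, or 0.29 with the median of its probes), CNN1 (0.27) and CNN2 (0.25), and the median was 0.08 (percentile 83.2). In the TGF-beta response list, 1 of 25 genes was beyond 2-fold, the inhibitor of DNA binding ID2 (2.31-fold higher), and with median scaling ID3 was also beyond it, at 1.03. The related ID3 and ID1 differed by 0.88 and 0.71 and the inhibitory SMAD7 by 0.70. The median of that list was -0.06 (percentile 3.22, or 2.24 with the median of a gene's probes) and its mean 0.07, so that median and mean had opposite signs. The percentile was 18.3 with cyclic loess, 20.5 with normexp and 25.6 with quantile normalization, and the mean stood at percentile 90.3 of random means. Of 25 measured metalloproteinases and inhibitors, 3 were at least 2-fold lower with IL-13 and none 2-fold higher. These were the collagenase MMP1 (2.19-fold lower over 10 spots), ADAMTS8 (2.06-fold) and ADAMTS15 (2.14-fold, among the dimmest 25%), and MMP10 differed by -0.97 (-0.23 with normexp, among the dimmest 25%). With median scaling each of the 3 was within 2-fold, with spike-in scaling 5 members were at least 2-fold lower, and ADAMTS15 differed by -0.35 with normexp. The median of this list was 0.02 (percentile 53.3) and the mean -0.17 (percentile 0.58 of random means).

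Among CC chemokines, CCL26 was the only one of 12 measured members beyond 2-fold, except that CCL3 was at -1.02 with spike-in scaling. CCL3 differed by -0.89 (-0.15 with normexp), CCL25 by 0.31 and CCL19 by -0.31 (0.15 and -0.04 with normexp), all among the dimmest 25%, and the median of the list was 0.02 (percentile 76.2). Of 6 measured CXC chemokines, CXCL1 differed by -1.23 at its brightest probe, but its other probe differed by 2.37, so no direction is given for it. CXCL12 was 1.79-fold higher at its brightest probe, but its 4 probes ranged from -0.55 to 0.84, so no direction is given for it either. CXCL5 (-0.07) and CXCL14 (0.04) were close to 0. CXCL10, named after its value was seen, was detected only without IL-13, at a bound of -2.18 on the log2 scale. The median of the CXC list was 0.01 (percentile 68.4), and -0.04 with the 2 members detected on 1 array at their bounds.

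The NF-kappaB inflammatory list went in both directions. IL6 and VCAM1 were at least 2-fold higher, whereas the IL-6 family cytokine LIF was 2.96-fold lower and the apoptosis inhibitor BIRC3 2.73-fold lower, with CXCL1 as the remaining member beyond 2-fold. Of 22 measured genes, 16 lay below 0, and 11 with median scaling. The median of -0.13, which is -0.14 relative to all genes, stood at percentile 0.77, and at 4.54 when a gene's probes were combined by their median. With the 3 members detected on 1 array at their bounds the median was -0.26. With normexp BIRC3 differed by -0.57, and with the median of its probes LIF differed by -0.99. The list held 1 member higher and 1 lower by 2-fold with normexp, and 2 and 1 with the median of probes. Interferon-stimulated genes showed no 2-fold difference among 29 measured. IFIT1 differed by -0.68, IFIH1 by 0.43, IFI44L by -0.41 and OASL by -0.41 (-0.16 and -0.06 with normexp), and the median was 0.02 (percentile 55.8) with a mean of -0.02.

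Cell cycle genes were slightly lower with IL-13 as a group. None of 36 measured members was beyond 2-fold, but 27 lay below 0 (18 with median scaling, 32 with spike-in scaling), including the mitotic genes HMMR (-0.45), KIF20A (-0.44), CCNB1 (-0.43) and CENPF (-0.42). The S phase genes, named after their values were seen, were mixed. MCM2 to MCM7 lay between -0.02 and 0.28, while PCNA (-0.15) and TYMS (-0.14) were lower. The median of -0.15, which is -0.16 relative to all genes, lay below all 10000 matched random lists. Targets of p53 and genes of cell cycle arrest were within 2-fold in all 20 cases. GDF15 and CDKN2B each differed by -0.61 (CDKN2B by -0.26 with normexp), SESN2 by 0.37 and GADD45A by 0.32, with a median of 0.05 (percentile 66.9) and a mean of -0.01. Of 25 measured immediate early genes, NR4A2 was the only one beyond 2-fold. KLF4 (-0.93) and FOS (-0.85), both among the dimmest 25%, and SPRY4 (-0.68) followed. KLF4 was at -1.06 with spike-in scaling, so that 2 genes were then beyond 2-fold, while with normexp KLF4 was at -0.25 and FOS at -0.26. The median of the immediate early list was -0.01 (percentile 30.6). It was 0.06 (percentile 92.4) with the median of a gene's probes, 0.08 (percentile 95.7) without the dimmest 25% of detected probes and -0.11 (percentile 0.85) without a filter on dim probes, and the mean stood at percentile 0.87, so no direction is given for this list.

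The unfolded protein and amino acid stress list and the cholesterol synthesis list had higher medians with IL-13, without any member reaching 2-fold. In the first, 14 of 24 measured genes lay above 0 and 10 below, and the largest differences were in PSAT1 (0.77, serine synthesis), ASNS (0.67, asparagine synthetase), MTHFD2 (0.64, mitochondrial folate metabolism) and the stress-response gene DDIT4 (0.54). The endoplasmic reticulum chaperone genes and cofactors HSPA5, HSP90B1, DNAJB9, DNAJC3, SDF2L1, PDIA4 and CALR, named after their values were seen, lay between -0.13 and -0.02. The median of that list was 0.18, or 0.17 relative to all genes. In the cholesterol synthesis list 16 of 19 measured genes lay above 0, including INSIG1 (0.37), LSS (0.36) and MVK (0.27), with a median of 0.20, or 0.19 relative to all genes. Both medians lay above all 10000 matched random lists. Hypoxia and glycolysis genes had a median of 0.07 over 27 members (percentile 75.9). The hexokinases went opposite ways, HK1 at 0.99 (1.14 with median scaling) and HK2 at -0.92 (-1.04 with spike-in scaling), while NDRG1 differed by -0.72 and LDHA by 0.29.

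WNT and BMP signalling genes went both ways, with 2 of 21 measured members at least 2-fold higher and 4 at least 2-fold lower. The WNT inhibitor NKD2 was 3.45-fold lower, the ligand WNT16 2.32-fold lower and the secreted antagonist DKK1 2.25-fold lower, whereas the ligand WNT2 was 2.62-fold higher at a dim signal. INHBA (1.15) and BMP2 (-1.08) were the remaining members beyond 2-fold, chosen after their values were seen. BMP2 was at -0.94 with median scaling, which left 3 members higher and 3 lower by 2-fold. With normexp WNT2 differed by 0.66, WNT16 by -0.98 and DKK1 by -0.96. The median was -0.13 (percentile 0.1), which is -0.14 relative to all genes. Growth factors and prostanoid enzymes had the lowest median of the lists with more than 6 measured members, -0.28 over 24 genes, or -0.29 relative to all genes, below all 10000 matched random lists. The phospholipase PLA2G4A was 2.11-fold lower over 10 spots (log2 difference -0.93 with median scaling and -0.88 with normexp), and HBEGF (-0.89, or -1.02 with spike-in scaling), FGF5 (-0.86) and the cyclooxygenase PTGS1 (-0.77) were within 2-fold.

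**Figure D2:**
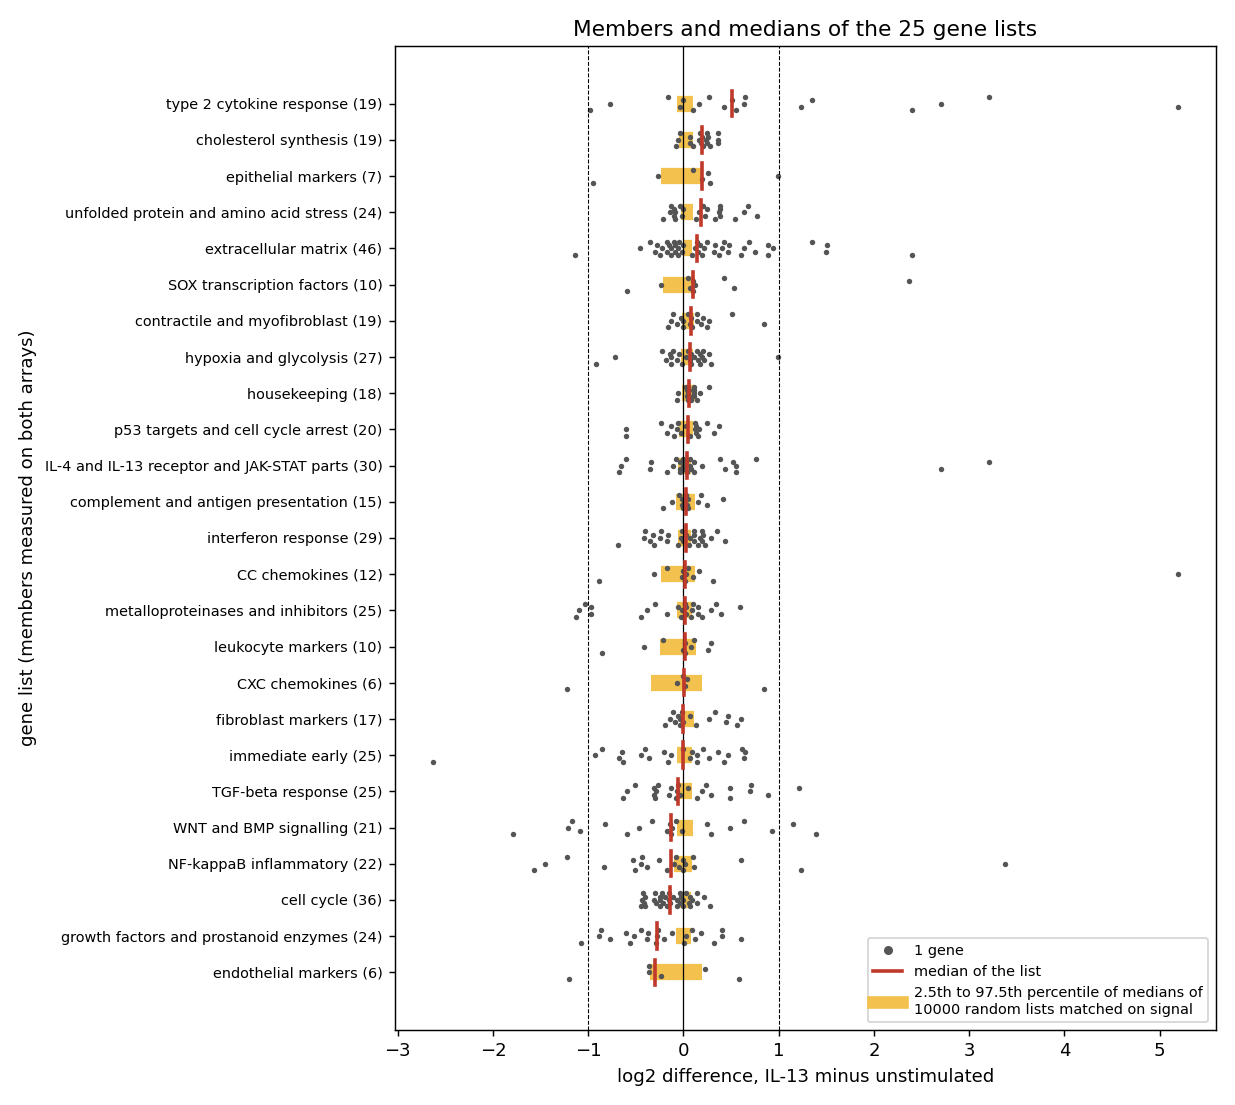
Log2 difference (horizontal axis, IL-13 minus unstimulated) of each measured member of the 25 gene lists (rows, number of members in brackets); grey points are genes, red marks the median of each list, and yellow bars span the central 95% of medians of 10000 random lists matched on signal. The type 2 cytokine response list has the highest median, 0.51, and the endothelial marker list, with 6 members, the lowest, -0.30.

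Genes detected on only 1 array have a bound in place of a fold. On the IL-13 array alone, 117 genes were well above background at a level at least 2-fold above the floor of the other array, and on the unstimulated array alone 125 genes were. The largest bounds with IL-13 were in IL1RL1, the IL-33 receptor (at least 11.9-fold higher), the endothelial tight junction gene CLDN5 (at least 10.7-fold), the transcription factor IRX3 (at least 8.66-fold), the long noncoding RNA LETR1 (at least 7.62-fold) and the calcium channel gene CACNA1D (at least 7.05-fold). The largest bounds without IL-13 were in MUC22 (at least 15.0-fold lower with IL-13), the olfactory receptor OR10A3 (at least 14.6-fold), the invariant chain CD74 (at least 12.1-fold), the cytochrome CYP2C8 (at least 10.8-fold) and CRB3 (at least 7.66-fold). Each came from 1 spot. MUC22 had 3 probes in all and IL1RL1 and LETR1 had 2 each, and their other probes were not well above background on either array. With a normexp background the counts were 12 and 7, and these bounds were smaller, from 1.18 to 1.63 on the log2 scale for the first 5 and from -1.70 to -1.14 for the others. The normexp offset shrinks such bounds by construction, so this drop does not show that the genes were unchanged.

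Complement and antigen presentation genes were all within 2-fold among the 15 measured on both arrays, while CD74, also of this list, was detected only without IL-13 (at least 12.1-fold lower with it). C4A and CFI, named after their values were seen, were detected only with IL-13, at bounds of 0.66 and 0.88 on the log2 scale. SERPING1 differed by 0.41 (0.19 with the median of its probes), C1R by 0.25 and CFD by -0.21, with a median of 0.03 (percentile 44.9). The 18 housekeeping genes had a median of 0.06 (percentile 47.3), with TUBB at 0.27 (0.12 with the median of its probes), RPS18 at 0.17, RPL13A at 0.14 and RPLP0 at 0.11; with spike-in scaling RPLP0 was at -0.02. The 17 fibroblast markers had a median of -0.003 (percentile 11.8) and a mean of 0.13, with DCN at 0.60, TBX5 at 0.56 (second probe 1.38), LUM at 0.47 and DDR2 at 0.44. The fibroblast percentile was 77.9 with cyclic loess and 61.7 with quantile normalization, and the mean stood at percentile 94.9. Of 16 epithelial markers 7 were measured on both arrays, with a median of 0.19 (percentile 97.9), and the keratins went opposite ways, KRT18 at 0.99 (1.13 with median scaling) and KRT19 at -0.95 (-1.08 with spike-in scaling), with KRT8 at 0.28 (0.02 with normexp) and CLDN4 at -0.26. The epithelial median stood at percentile 96.8 with normexp and 96.0 with the median of a gene's probes, and the mean at 81.8. Without a filter on dim probes the median relative to all genes was -0.002 (percentile 76.6). Of 6 measured endothelial markers, ROBO4 was 2.30-fold lower near background (log2 -0.27 with normexp), KDR differed by 0.58 (0.16 with normexp), TEK by -0.36 and VWF by -0.36, and the median was -0.30 (percentile 4.88, or 0.17 with normexp). The endothelial percentile was 30.1 without a filter on dim probes, and the mean stood at percentile 17.1. CLDN5, also of this list, was detected only with IL-13, at least 10.7-fold higher, and with it at its bound the median was -0.23. Leukocyte markers were within 2-fold in all 10 measured cases, with CSF1R at -0.85 (-0.17 with normexp, among the dimmest 25%), KIT at -0.42, NKG7 at 0.29 (0.09 with normexp) and ITGAM at 0.25, a median of 0.02 (percentile 74.2) and a mean of -0.07. The second probe of KIT differed by -1.07, and the median of its probes by -0.75.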

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

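The test of NF-kappaB targets below was chosen only after the result it bears on was seen, while the other tests were set out before their own outcomes were seen. The IL6 and cell cycle tests concern patterns that were picked out from these same arrays. Signal outside the named genes appeared in 48 probes without a gene symbol, which were at least 2-fold higher with IL-13 among 6395 such probes measured on both arrays, while 130 were at least 2-fold lower. Of these, 41 and 122 lay at or below the signal that bounds the dimmest 25% of named genes.

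The number of 2-fold differences was weighed against spot-to-spot noise. In the dimmest 25% of genes 147 of 3770 differed 2-fold, and simulations that added replicate-spot noise alone gave up to 196 (mean 163). However, the median SD of the log2 difference between replicate spots was 0.264 for the dimmest replicated probes, and 3 SD lies below 2-fold. Simulated counts this high need wider noise than that median SD describes. The noise put into the simulations thus did not match the spread measured at those probes. For that reason the comparison cannot decide whether noise near background accounts for the 147. In the brighter 75% 102 of 11310 differed 2-fold, while the highest of the 100 simulations gave 11, which argues against noise between spots as the whole cause there. Differences between dishes, labellings or hybridisations unrelated to IL-13 cannot be told apart from an effect of IL-13, since the number of arrays per group is 1. An effect of IL-13 on the 59 higher and 43 lower bright genes stays open as the biological explanation.

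IL6 was 10.4-fold higher, while 16 of the 22 measured genes of the NF-kappaB list lay below 0 (11 with median scaling). Without IL6, the median log2 difference over the other 21 was -0.17. The median with IL6 was already -0.13, and leaving out the highest member could not raise it. The sign of this value was thus known beforehand, so it cannot decide on a general activation of NF-kappaB target genes. In these values the other 21 were not higher as a group. A single faulty spot for IL6 cannot be excluded, because the array holds 1 measured spot of 1 probe (as for CCL26, CISH and SOCS1), and the number of other IL6 probes or spots with a difference above 1 was 0 for lack of any. A selective effect of IL-13 on IL6 is a hypothesis that this pair of arrays leaves open.

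The cell cycle list was lower with IL-13 by a small amount in 27 of its 36 genes (18 with median scaling, which shifts all genes up). After cyclic loess, which removes an intensity-dependent trend between the arrays, its median relative to all genes was still -0.15 and below all 10000 matched random lists, so such a trend is unlikely to be the whole cause. A different growth state of the dishes unrelated to IL-13, for instance in cell density, cannot be told apart from an effect of IL-13 with 1 array per group. Fewer dividing cells with IL-13 may be one biological explanation, and it stays untested. The S phase genes MCM2 to MCM7 were not lower as a set (-0.02 to 0.28), while PCNA (-0.15) and TYMS (-0.14) were.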

How the results depend on the processing

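Spike-in scaling and the spot-SD threshold were chosen after the values were seen. List medians are relative to all genes here. They and their percentiles cannot move where a setting adds 1 constant to all genes or, like the filter on saturated spots, removes none. In the other settings 178 list medians moved by less than the median SD between replicate spots (0.0867), 20 by more, and 2 that were larger than this SD turned sign. Of the gene values 247 moved by more than the spot SD, and 1 beyond 2-fold turned sign, CXCL1, at 0.57 with the median of its probes, as did 6 small differences (STAT6, IL4R, IL13RA1, CXCL5, CXCL14 and RPLP0) under one scaling or another. Of the bounds 90 stayed within the spread and 10 moved, all with normexp. Where not stated otherwise, the cause was not tested.

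Of the counts 36 stayed within 1.5 times their value and 14 did not. Median scaling left 80 lower genes, all among the 129, and spike-in scaling gave 213, since each adds 1 constant to all genes. Normexp gave 50 higher, 33 lower, and 12 and 7 genes on 1 array only, and kept 50 of the 120 and 29 of the 129. Its offset shrinks dim differences by construction. Without a filter on dim probes 582 genes were higher and 1053 lower, more genes being counted. The medians were then 0.17 for type 2, -0.10 for endothelial markers, and of turned sign for SOX (-0.0669) and epithelial markers (-0.0016). Leaving out the lower quartile of signal gave 75 and 62 from fewer genes, with NF-kappaB at -0.23 and leukocyte markers at -0.0918. At 1.5-fold the counts were 366 and 566, and at 3-fold 40 and 34, by construction. Quantile normalization and loess raised SOX (0.22 and 0.21), CXC chemokines (0.15 and 0.14) and leukocyte markers (0.10 and 0.11).

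Means in place of medians, which weigh outlying members more, gave 0.93 for type 2, 0.23 for receptor and JAK-STAT, 0.30 for SOX, 0.27 for matrix, 0.0754 for TGF-beta, -0.16 for metalloproteinases, 0.38 for CC chemokines, -0.15 for immediate early genes, 0.14 for fibroblast and -0.21 for endothelial markers. The type 2, matrix, cholesterol and stress lists stayed above the central 95% of random lists, and the cell cycle, WNT and BMP, and growth factor lists below it, in every setting run. NF-kappaB did not, at 4.54 with the median of probes and 8.09 with means. Of the percentiles that could move, 17 crossed a limit of that range and 208 did not. The spot-SD threshold and the filter on saturated spots could not remove a 2-fold gene and test nothing. As set here, 3 SD lay below 2-fold at every signal, and 0 spots were saturated. For genes dimmer than the median of the dimmest eighth of replicated probes (-3.75), that SD was held at 0.264. Their own spread was not used.

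No paired analysis was possible because each group has 1 array, and for the same reason no replicate was left out and no slide block fitted. Signal over background limits the dimmest 25% of genes most.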

Other observations

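The gene families described here were chosen after the values were seen, and no explanation for them was tested. Metallothioneins, zinc- and copper-binding proteins, were lower with IL-13. Of 12 genes of the family 9 were measured on both arrays, all 9 lay below 0 (8 of 9 with median scaling), and 6 were at least 2-fold lower (0 with median scaling, which shifts all genes up, 5 with normexp and 5 with the median of probes). These were MT1X (-1.11, with its other probe at -0.64), MT1E (-1.11), MT1F (-1.10), MT1HL1 (-1.06), MT1B (-1.05) and MT1M (-1.05), while MT1A differed by -0.91, MT2A by -0.25 and MT3 by -0.07. The median was -1.05, or -1.06 relative to all genes. The MT1 genes are close paralogs, and their probes were not shown to be specific, so the 6 values are not independent.

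Among 21 measured interleukin receptor chains of 37, 4 were at least 2-fold higher with IL-13 and none 2-fold lower. IL17RA was 3.35-fold higher, with its 3 probes between 1.74 and 2.61 on the log2 scale, and IL18R1 was 2.66-fold higher, with the lowest of 3 probes at 0.88. IL21R was 2.44-fold and IL20RB 2.195-fold higher, the latter pair each from 1 probe. The median of the family was -0.03, and with normexp 2 chains were at least 2-fold higher. IL1RL1, the IL-33 receptor, was detected only with IL-13, and its other probe was not well above background on either array.

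PTGS2, the inducible cyclooxygenase, was also chosen after its value was seen. It was well above background only without IL-13, at a bound of -2.62 on the log2 scale.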
